A study of Mus musculus with 9 samples.

How the data were processed

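The data were RNA-seq libraries of C2C12 cells, an established line of mouse myoblasts that can form muscle fibres in culture. Per the labels' protocols, the cells were kept in DMEM with fetal bovine serum, and after attaching they received butyrate or pentanoate at 750 µM for 48 h. One label text names the first compound as butyric acid and others name it butyrate, and it is called butyrate here. What the control cells received is not given in the sources used here. RNA was taken up in Trizol and libraries were made with a SMARTER mRNA kit, per the labels' protocols. The labels give 3 groups (control, butyrate, pentanoate) of 3 libraries each, numbered 1 to 3 in every group.

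The deposited table holds raw counts per gene, with the authors' gene symbols, Ensembl identifiers and coordinates, and the values in the 9 library columns are whole numbers with a different total in each library. Per the submitters' processing notes, the genome build was GRCm38 (mm10). The aligner, the counting program and whether counting used the strand are not given in the sources used here, so reads shared between overlapping genes or between near-identical genes cannot be assigned with certainty. Of the 54697 table lines, 54532 carry an Ensembl identifier and 165 do not, and 54495 identifiers were found in GENCODE release M21 of the mouse annotation, 53585 of them with identical coordinates. Lines without an identifier took 0.0918% to 0.107% of a library's counts. They were kept, and 110 of them were tested. A total of 28190 lines had no count in any library.

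Counts were used as deposited. The filter filterByExpr of edgeR left 14066 genes, 12088 of them annotated as protein-coding. Library sizes were scaled by TMM. The main test was edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) with all 9 libraries in a single fit and the group as the sole factor, which leaves 6 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05. Fold changes are fitted log2 values with the default prior count of edgeR, given with standard errors and 95% confidence intervals, and CPM values use the TMM-scaled library sizes. The standard errors were not taken from the fit. Each is the size of the log2 change divided by the square root of the test's F value, and the intervals use it with the t distribution. Both are approximate, above all for genes with few counts or changes near 0. The common biological coefficient of variation was 14.4%. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

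A set of 41 gene lists was fixed before the data were examined. It covers myogenic regulators, contractile proteins, the cell cycle, metabolism, signalling, stress and inflammation, together with markers of neuronal, blood, epithelial and endothelial, adipocyte, and osteoblast and chondrocyte cells. Each list was tested with camera of limma, with a preset correlation between genes of 0.01, and p-values were adjusted over the 41 lists within a comparison. Camera with an estimated correlation and fry (limma) were run beside it. Member counts are given over all genes tested and adjusted over the list alone. Principal components used log2 CPM (prior count 2) of the 500 most variable genes.

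The genes to name were also fixed by a rule before the data were examined. It takes protein-coding genes called with no overlap between the 3 and 3 libraries and at least 1 CPM on average in either group, and of these the 8 largest rises and 8 largest falls against control, or 5 and 5 between the acids. It adds the 3 members of smallest p in each called list, and Myod1, Myf5, Myog, Mymk, Myh3, Ckm, Cdkn1a, Ccnd1, Mki67, H1f0, Hdac1, Hdac2, Slc16a1 and Pdk4 whatever their result. Ckm had 14 counts in all libraries together and was not tested. The text prints part of the genes the rule gives, chosen with a view to how stable their calls were. Over all of them, 40 of 53 called genes kept the call for butyrate against control in the scaling by DESeq2 size factors, the DESeq2 Wald test, the replicate block and each omission of a library. The same holds for 6 of 14 genes for pentanoate against control and 11 of 52 for pentanoate against butyrate.

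Replicate numbers come from the labels, and they paired the libraries by a criterion set beforehand. Deviations from the group means correlated at r = 0.20 to 0.41 over genes in all 9 same-numbered pairs, above the criterion of 0.1, and at −0.33 to 0.013 in the 18 other pairs. The deviations within a group cancel out for each gene, so higher values in same-numbered pairs force lower ones in the others. The other pairs are therefore no independent contrast. A fit with the replicate number as a block is therefore given beside most results whose call it changes or whose count it moves by over 1.5 times. Some small counts of list members are given without it. No replicate pair was a repeat of the same library: the chi-square per degree of freedom between counts of libraries of a group was 8.04 to 12.6, and 46.3 and 60.7 where control 3 was part of the pair.

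Both acids were compared with the same 3 controls, which makes their fold changes correlate by chance. Unchanged groups were therefore simulated against those controls 30 times for correlation and covariance and 10 times for calls and signs, without an effect of the replicate number. Added after the data were seen, 30 further simulations for correlation and covariance drew the unchanged groups with the fitted effect of each number and were fitted with the block. The test steps were tested on simulated data with 3 draws for each comparison with control, each of 14066 genes with 200 of them changed. For butyrate against control, the test called 32.8% of genes changed 1.5-fold, 71.1% of those changed 2-fold and 91.4% of those changed 4-fold. For pentanoate against control these shares were 33.3%, 68.7% and 86.4%. Of the simulated calls, 7.72% and 6.45% fell on unchanged genes, somewhat above the nominal share, and 0 had the wrong direction. The comparison between the acids was not simulated.

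The alternatives tried were other scalings (DESeq2 size factors, upper quartile, library totals), the DESeq2 Wald test, limma-voom, no filter or a filter at a mean of 5 CPM, a fit of the 2 groups compared alone, the replicate block, a minimum change of 2-fold, and the omission of each library in turn. Added after the data were seen were the block without control 3, the block with trends in GC content and gene length removed, the table without mitochondrially encoded genes, and the omission of each library for 37 of the 41 lists. Totals of 15829262 to 19305981 counts gave tested genes a median of 461 counts per library. For genes with 0 counts in a group, a lower bound on the fold was taken against a floor of 3 counts over the group, and for genes with 1 to 3 counts the ratio is given with its 95% interval. These bounds and intervals cover counting error only.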

Results

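Gene expression was measured by RNA-seq in C2C12 cells, a mouse myoblast line, after 48 h with 750 µM butyrate, with 750 µM pentanoate, or in control cells, with 3 libraries per group. The series title names myogenic effects of both acids as the question. Total counts were 17317580, 18102783 and 15829262 in control libraries 1 to 3, 16798613, 16545507 and 16295320 in the butyrate libraries and 19305981, 18192492 and 18041090 in the pentanoate libraries. Values are raw counts per gene as deposited, scaled to CPM, and 14066 genes were tested. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread among these samples, which may be technical.

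The groups separated along the first principal component, which held 56.9% of the variance of the 500 most variable genes. Control libraries scored −21.9 to −19.7 on it, pentanoate libraries −4.62 to 0.411 and butyrate libraries 18.7 to 24.6. The second component (17.8%) followed the replicate numbers, with control 3 at −16.7. Control 3 also stood apart in the share of counts from mitochondrially encoded genes, 3.95% against 2.32% and 1.97% in controls 1 and 2, 1.96% to 2.28% with butyrate and 1.80% to 2.22% with pentanoate. Over genes, the fold change against control rose with GC content, with Spearman's rho of 0.23 for butyrate and 0.46 for pentanoate, and without control 3 these were −0.057 and 0.086. Genes are not independent replicates, so these correlations carry no p-value. Between the acids, where control 3 takes no part in the difference, rho was 0.13. Odorant, vomeronasal and taste receptor genes, taken as a measure of background reads, summed to 10.2 to 20.2 CPM in control, 14.4 to 20.3 with butyrate and 8.85 to 17.5 with pentanoate.

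**Figure D1:**
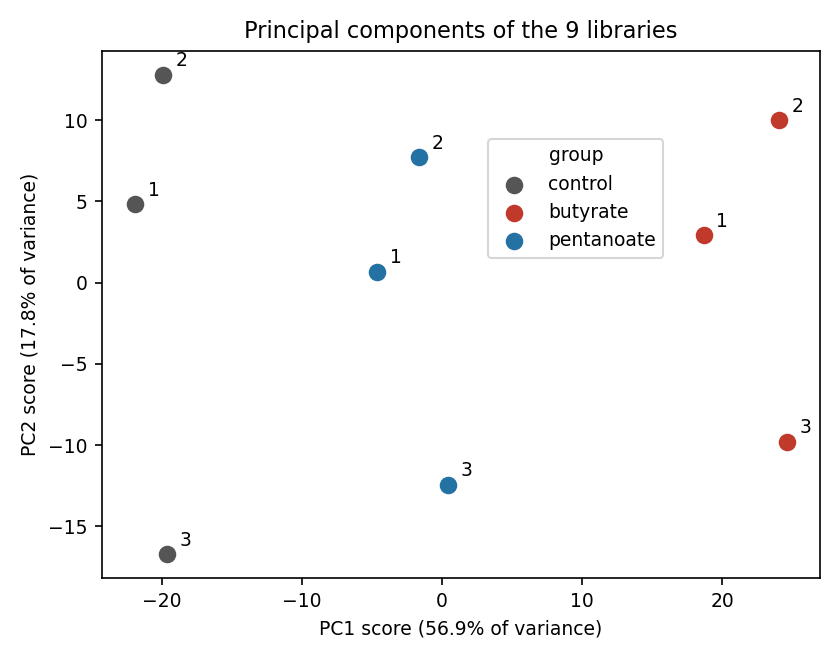
Scores of the 9 libraries on principal components 1 (x axis, 56.9% of the variance) and 2 (y axis, 17.8%) of log2 CPM of the 500 most variable genes, coloured by group and marked with the replicate number. Pentanoate libraries lie between control and butyrate libraries on the x axis, and libraries numbered 3 lie lowest on the y axis.

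Compared with control cells, butyrate-treated cells held less RNA of several genes that act in muscle differentiation and contraction. Mymk (ENSMUSG00000009214, chromosome 2, 27061636 to 27072179), which encodes the membrane protein myomaker that drives myoblast fusion, fell by 2.82 on the log2 scale (SE 0.41, adjusted p = 0.00201), from 4.13 ± 1.46 CPM to 0.575 ± 0.329 (SD, n = 3 each). Acta1 (ENSMUSG00000031972, chromosome 8, 123891769 to 123894751), the skeletal muscle actin gene, fell by 2.59 (SE 0.23, adjusted p = 0.000161), from 11.2 ± 0.857 to 1.85 ± 0.456 CPM. Myod1 (ENSMUSG00000009471, chromosome 7, 46376474 to 46379099), a transcription factor that sets muscle identity, fell by 0.89 (SE 0.17, adjusted p = 0.00828), from 84.3 ± 13.1 to 45.5 ± 10.1 CPM. Klhl40, a protein of the sarcomere, fell by 2.33 (SE 0.42, adjusted p = 0.0057) from a low level of 1.13 ± 0.084 CPM.

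Of the late myogenic regulators and fusion genes, 8 of 23 fell and none rose, 10 adjusted over the list alone, with a median log2 change of −0.46 (camera, adjusted p = 0.00014, and adjusted p = 0.32 with an estimated correlation). With the filter at a mean of 5 CPM the late myogenic list was not called (adjusted p = 0.17). Of the sarcomere and contractile genes, 10 of 30 fell and 1 rose, 13 and 1 adjusted over the list alone, with a median of −0.80 (adjusted p = 3.4e-05, and adjusted p = 0.32 with an estimated correlation). Myog, the transcription factor myogenin, and Myh3, the embryonic myosin heavy chain, fell by 2.75 (SE 0.74) and 2.81 (SE 0.76), with adjusted p = 0.0366 and 0.0369. The call of Myog was lost without control 1, control 3, butyrate 2 or butyrate 3 (adjusted p 0.0745 to 0.131), and that of Myh3 without control 1 or any butyrate library (0.0614 to 0.14). Myf5, an early myogenic factor, rose by 0.57 (SE 0.14, adjusted p = 0.0279), a call lost without control 1, control 2 or any butyrate library (0.0552 to 0.094). The list of myoblast identity and early regulators, with 1 rise and 4 falls among 23 members (2 and 7 adjusted over the list alone) and a median of −0.23, had an adjusted p = 0.06. With the block 8 fell, 2 rose and the list was called (adjusted p = 0.044, and adjusted p = 0.21 with the block and an estimated correlation), and it was also called without control 3 (0.029) and without butyrate 1 (0.026). Excitation-contraction coupling and synapse genes, with 3 rises and 5 falls among 24 (3 and 7 adjusted over the list alone), had a median of −0.44 and an adjusted p = 0.06. With the block 13 of them fell and the list was called (adjusted p = 0.0028, and adjusted p = 0.12 with the block and an estimated correlation), as it was without control 2, control 3 or butyrate 1 (0.0068 to 0.031).

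Smooth muscle and myofibroblast markers were lower as well, with 6 of 12 falling (7 adjusted over the list alone, 10 with the block) and a median of −0.74 (adjusted p = 1.6e-05, and adjusted p = 0.32 with an estimated correlation). Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255336), the smooth muscle actin gene and an abundant transcript, fell by 1.17 (SE 0.10, adjusted p = 0.000161), from 3671 ± 277 to 1634 ± 142 CPM. Cnn1, which encodes calponin, fell as well (95% interval −1.59 to −0.91 on the log2 scale, adjusted p = 0.000731), from 59.5 ± 9.05 CPM in control. The actin genes Acta1, Acta2, Actc1 and Actg2 are near-identical in their coding parts, and how the counting shared reads between them is unknown, so their separate values are uncertain. In control 3 the smooth muscle list lay 0.54 below the mean of controls 1 and 2 (median log2 ratio −0.54), where controls 1 and 2 differed by −0.02. The sarcomere list lay at −0.28 in control 3, less than the median of 0.50 by which controls 1 and 2 differed. Aoc3 (ENSMUSG00000019326, chromosome 11, 101330605 to 101341938), a cell-surface amine oxidase, fell by 3.20 (SE 0.13, adjusted p = 1.41e-06), from 30.7 ± 1.47 to 3.33 ± 0.237 CPM. Among the largest falls were also Cilp (−3.75, SE 0.48, adjusted p = 0.000936), Tenm4 (−3.03, SE 0.48, adjusted p = 0.00288) and Ecm2 (−2.87, SE 0.43, adjusted p = 0.00228), which encode a cartilage matrix protein, a teneurin and an extracellular matrix protein.

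The largest rises with butyrate were in genes almost without counts in control cells. Tbkbp1 had 78 counts over the butyrate libraries and 0 in control, at least 26.2-fold higher against a floor of 3 counts over the control group, and the 95% counting interval of its ratio reaches down to 20.8. The ratio of Ccdc184 was 92.1 (95% interval 25.1 to 766), that of Klra2 85.6 (14.9 to 3420), that of the homeobox gene Tlx2 73.5 (12.8 to 2940) and that of the peptide hormone gene Cck 54.7 (18.4 to 268), with adjusted p from 0.000361 to 0.00231 for these 5 genes. Ramp3, a receptor accessory protein, rose by 5.45 (SE 0.67, adjusted p = 0.000743), from 0.105 ± 0.136 to 4.66 ± 2.28 CPM.

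Neuronal markers rose together, 6 of 9 (7 adjusted over the list alone), with a median of 1.15 (adjusted p = 1.9e-07, and adjusted p = 0.036 with an estimated correlation). Of the 24 markers listed, 9 passed the filter and were tested. A marker nearly silent in control could pass it through a treated group, which favours rises among those tested. How many passed that way was not examined. L1cam (ENSMUSG00000031391, chromosome X, 73853778 to 73896105), a neural cell adhesion molecule, rose by 3.14 (SE 0.29, adjusted p = 0.000222), from 0.848 ± 0.21 to 7.55 ± 1.53 CPM. Mapt, which encodes tau, rose by 3.56 (SE 0.40, adjusted p = 0.000498), and Stmn2 (ENSMUSG00000027500, chromosome 3, 8509360 to 8561606), a regulator of microtubules in neurons, rose by 1.15 (SE 0.10, adjusted p = 0.000161), from 13.7 ± 0.331 to 30.4 ± 1.68 CPM. Of the genes commonly raised by deacetylase inhibitors, a class of compound that includes butyrate, 7 of 17 rose (10 adjusted over the list alone and 11 without control 3) with a median of 0.54 (adjusted p = 1.6e-05, and adjusted p = 0.046 with an estimated correlation). Among them were Cited2 (0.84, SE 0.14, adjusted p = 0.00373) and Txnip (0.71, SE 0.14, adjusted p = 0.00798), an inhibitor of thioredoxin. H1f0, a linker histone, rose by 0.44 (SE 0.10, adjusted p = 0.0184), a call lost without butyrate 2 (0.0915) or butyrate 3 (0.064). Hdac1, a deacetylase, rose by 0.43 (SE 0.10, adjusted p = 0.015), a call lost without control 1 (0.059) or butyrate 2 (0.0697), and Hdac2 stood at −0.20 (SE 0.10, adjusted p = 0.242).

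Glycolysis and hypoxia response genes rose in 11 of 31 cases, 18 adjusted over the list alone with 1 fall, and 17 rose with the block. Their median was 0.40 (adjusted p = 8e-07, and adjusted p = 0.046 with an estimated correlation). The glycolytic enzymes Pgam1 (0.52, SE 0.09, adjusted p = 0.00404), Tpi1 (0.54, SE 0.10, adjusted p = 0.00479) and Pgk1 (0.53, SE 0.09, adjusted p = 0.00512) were among them. Gapdh, also a glycolytic enzyme gene, was counted unevenly, at 102, 15.9 and 11.5 CPM in controls 1 to 3. How the counting shared reads between near-identical genes is unknown, so values of glycolytic genes are uncertain in every comparison. Of the p53 targets, 7 of 25 rose, 16 with 1 fall adjusted over the list alone and 13 with the block, with a median of 0.44 (adjusted p = 4.2e-06, and adjusted p = 0.20 with an estimated correlation). Ccng1, an atypical cyclin, rose by 0.80 (SE 0.15, adjusted p = 0.0081). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose by 0.77 (SE 0.19, adjusted p = 0.0277), a call lost without butyrate 1 (0.0583) or butyrate 2 (0.13). Oxidative stress genes and metallothioneins rose in 8 of 28 cases with 1 fall (11 and 1 adjusted over the list alone), with a median of 0.26 (adjusted p = 0.00015, and adjusted p = 0.32 with an estimated correlation), among them the quinone reductase Nqo1 (0.94, SE 0.17, adjusted p = 0.00597). Inflammatory mediators rose in 6 of 20 cases (7 adjusted over the list alone), with a median of 0.48 (adjusted p = 0.00033, and adjusted p = 0.11 with an estimated correlation). Cxcl1 (ENSMUSG00000029380, chromosome 5, 90891241 to 90893115), a chemokine of neutrophils, rose by 2.13 (SE 0.16, adjusted p = 0.000103), from 6.64 ± 0.613 to 29.0 ± 3.69 CPM, and Il33 and Csf1 rose by 1.89 (SE 0.25) and 1.12 (SE 0.15).

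Among cell cycle genes, Ccnd1, which encodes cyclin D1, rose by 1.04 (SE 0.18, adjusted p = 0.00427). No S phase gene of 41 was called (0 adjusted over the list alone), and the list, with a median of 0.15, had an adjusted p = 0.06. With the block 9 of its members rose and the list was called (adjusted p = 0.0032, and adjusted p = 0.53 with the block and an estimated correlation), as it was without control 2, control 3 or butyrate 1 (0.0068 to 0.011) and with the filter at a mean of 5 CPM (0.011). Between controls 1 and 2 the S phase list differed by a median of −0.37, and control 3 lay at 0.18 to them. Both are larger in size than the median of 0.15 with butyrate. No G2 and M phase gene of 52 was called (0 adjusted over the list alone), the median was −0.03 and the adjusted p was 0.72, and without control 1 the list was called lower (0.031). The proliferation marker Mki67 stood at 0.17 (SE 0.13, adjusted p = 0.452, and 0.0219 without control 3). Slc16a1, a monocarboxylate transporter that carries short-chain fatty acids, rose by 0.57 (SE 0.11, adjusted p = 0.00798), and Pdk4, a kinase that inhibits pyruvate dehydrogenase, fell by 0.86 (SE 0.09, adjusted p = 0.00035).

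Mitochondrially encoded genes had a median of −0.53 with butyrate (adjusted p = 0.025, and adjusted p = 0.6 with an estimated correlation), with 0 of 13 called (0 adjusted over the list alone). In control 3 the same list lay at a median log2 ratio of 0.90 to controls 1 and 2, and all tested genes of the mitochondrial chromosome, most of the others for transfer RNA, at 0.55. Between controls 1 and 2 the list differed by 0.18, and without that library the list was not called (adjusted p = 0.32), nor was it without butyrate 2 (0.055). Adipocyte markers, with 1 rise and 2 falls among 11, and osteoblast and chondrocyte markers, with 2 falls among 15, were not called (adjusted p = 0.86 and 0.96). Adjusted over the list alone, these lists had 1 rise and 2 falls and 2 rises and 3 falls. The osteoblast and chondrocyte list had a median of 0.20 and a mean of −0.03, so its sign depends on the measure. With the block the osteoblast and chondrocyte list had 2 rises and 4 falls. For blood cell markers 1 of 5 rose (3 with the block) and for epithelial and endothelial markers 2 of 4, with 3 and 2 adjusted over the list alone and medians of 1.07 and 0.98 (adjusted p = 0.085 for both, and adjusted p = 0.32 for both with an estimated correlation). These lists name 18 and 24 markers, and the limit given for neuronal markers on passing the filter holds for them too. The blood cell list was called without control 1, control 2, control 3 or butyrate 3 (0.026 to 0.031), and the epithelial and endothelial list without control 1, control 2, butyrate 1 or butyrate 3 (0.028 to 0.049).

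In all, 1601 genes were called for butyrate against control, 905 higher and 696 lower (56.5% higher). All of the called genes had no overlap between the 3 and 3 libraries, as did 29.1% of the genes tested, where chance gives 10%. At a change of at least 2-fold, 517 were higher and 129 lower. With upper-quartile scaling 68.8% of the calls were higher, and with library totals 65.1%. The replicate block gave 2916 calls, 1516 higher and 1400 lower, and leaving out control 1, butyrate 2 or butyrate 3 left 953, 753 and 827. Of the 41 lists, 12 were called, 7 higher and 5 lower, and 3 held with an estimated correlation: neuronal markers, glycolysis and hypoxia response, and genes commonly raised by deacetylase inhibitors. With the block and an estimated correlation none of these 3 was called (adjusted p = 0.12 for each), and 0 lists were.

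**Figure D2:**
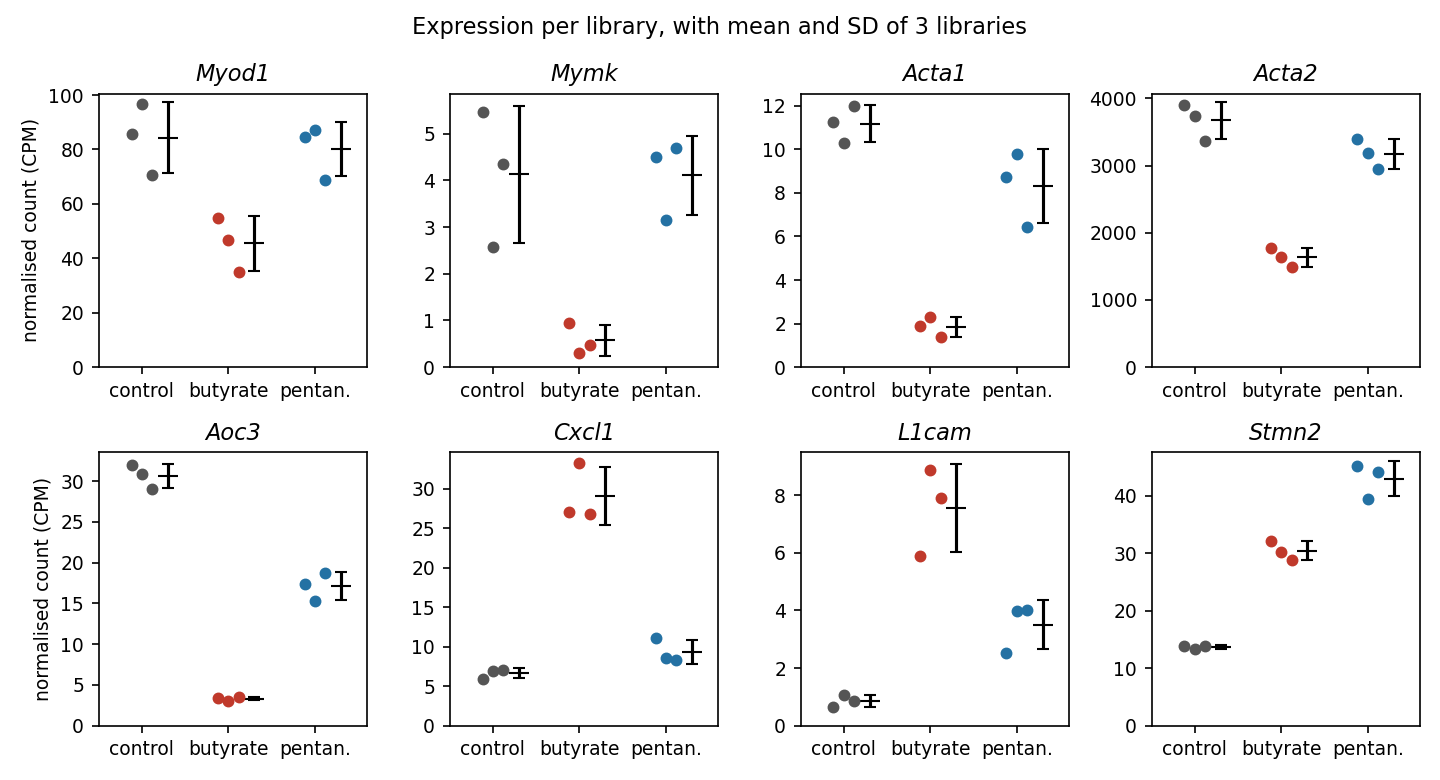
Normalised count in CPM (y axis, linear, from 0) of 8 genes in each library (points) by group (x axis: control, butyrate, pentanoate), with the mean and SD of 3 libraries as a line and bars. Myod1, Mymk, Acta1, Acta2 and Aoc3 are lowest with butyrate, Cxcl1 and L1cam are highest with butyrate, and Stmn2 is highest with pentanoate.

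With pentanoate, 110 of the 113 genes called against control in the test without the block were higher than in control cells, and with the block, where 514 were called, 91 were lower. Stmn2 rose by 1.65 (SE 0.10, adjusted p = 7.48e-05), from 13.7 ± 0.331 to 42.9 ± 3.02 CPM (SD, n = 3 each). Rtn4rl2 (ENSMUSG00000050896, chromosome 2, 84871924 to 84886710), a receptor of the Nogo receptor family, rose by 2.92 (SE 0.33, adjusted p = 0.00565), from 0.712 ± 0.221 to 5.44 ± 1.36 CPM. Cacna1g (ENSMUSG00000020866, chromosome 11, 94408391 to 94474198), a calcium channel subunit, rose by 2.89 (SE 0.34, adjusted p = 0.00565), from 0.312 ± 0.104 to 2.38 ± 0.335 CPM. Fam131c (2.55, SE 0.31, adjusted p = 0.00565), the cell adhesion gene Iglon5 (2.44, SE 0.33, adjusted p = 0.00839) and Egfl7 (2.38, SE 0.32, adjusted p = 0.00824) rose likewise. The 3 genes that fell were Aoc3 (−0.84, SE 0.12, adjusted p = 0.00839), Scfd2 (−0.84, SE 0.17, adjusted p = 0.0476) and Pdk4 (−0.59, SE 0.09, adjusted p = 0.0116). Their calls were lost without pentanoate 2 for Aoc3 (0.0545), without pentanoate 2 (0.0639) or pentanoate 3 (0.0784) for Pdk4, and without any control or pentanoate library for Scfd2 (0.0637 to 0.175).

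Neuronal markers rose with pentanoate in 3 of 9 cases, 6 adjusted over the list alone and 5 with the block, with a median of 1.36 (adjusted p = 3.4e-08, and adjusted p = 0.029 with an estimated correlation). The limit given above on how these 9 markers passed the filter holds here too. L1cam rose by 2.03 (SE 0.29, adjusted p = 0.0111), a call lost without control 1, pentanoate 2 or pentanoate 3 (0.0516 to 0.066). Mapt rose by 2.28 (SE 0.42, adjusted p = 0.0361), a call lost without control 1, control 2 or any pentanoate library (0.0755 to 0.136). Of the genes commonly raised by deacetylase inhibitors, 0 of 17 were called (0 adjusted over the list alone) while the list had a median of 0.29 (adjusted p = 0.03, and adjusted p = 0.35 with an estimated correlation), and it was not called without control 2 (0.13) or pentanoate 1 (0.06). Insulin and IGF signalling genes, 0 of 19 called (1 rise adjusted over the list alone, 4 rises with the block), had a median of 0.19 (adjusted p = 0.036, and adjusted p = 0.52 with an estimated correlation), and the list was not called without control 2, control 3 or pentanoate 1 (0.052 to 0.13). Mitochondrially encoded genes, 0 of 13 called (0 adjusted over the list alone), had a median of −0.51 (adjusted p = 0.03, and adjusted p = 0.8 with an estimated correlation), and without control 3, which held the highest share of these counts, or without pentanoate 2 the list was not called (0.18 and 0.072).

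Genes of muscle differentiation were not called against control with pentanoate. Mymk was at 4.11 ± 0.842 CPM against 4.13 ± 1.46 in control (log2 change 0.00, 95% interval −0.75 to 0.74), and Myod1 at 80.1 ± 9.84 against 84.3 ± 13.1 (−0.07, −0.45 to 0.30). For Myog the interval was −1.69 to 1.03 and for Myh3 −2.44 to 0.34, so changes of 2-fold could not be excluded for either. The late myogenic list had a median of −0.03 (adjusted p = 0.71) and the sarcomere list −0.05 (adjusted p = 0.53, and 0.045 without control 3), with 0 of 23 and 0 of 30 genes called, also adjusted over the list alone. The S phase and G2 and M phase lists, with medians of −0.03 and −0.01 and 0 genes called over all genes tested or adjusted over the list alone, had adjusted p = 0.98 and 0.84, and without control 1 both were called lower (0.049 and 0.021). Cdkn1a stood at 0.05 (95% interval −0.38 to 0.47) and Ccnd1 at 0.49 (SE 0.17, adjusted p = 0.261, and 0.0065 with the block). Myf5 stood at 0.34 (SE 0.14, adjusted p = 0.341, and 0.0348 without control 3). Glycolysis and hypoxia response genes had a median of 0.01 and a mean of 0.08 while camera gave the direction down, and the list was not called (adjusted p = 0.98). Blood cell, epithelial and endothelial, adipocyte, and osteoblast and chondrocyte markers were not called (adjusted p = 0.98, 0.23, 0.39 and 0.61), with 0 genes called over all genes tested or adjusted over the list alone. Hdac1, Hdac2, H1f0, Slc16a1 and Mki67 were not called either, with log2 changes of 0.23, −0.14, 0.29, 0.19 and 0.07.

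In all, 113 genes were called for pentanoate against control, 110 higher and 3 lower, with 1932 at an unadjusted p under 0.05. All of the called genes had no overlap between libraries, as did 18.5% of those tested. A change of at least 2-fold was reached by 72, all higher. The block gave 514 calls, 423 higher and 91 lower, and DESeq2 gave 324, 279 higher and 45 lower. In 2 settings chosen after the data were seen the share of falls was larger: the block with GC content and length trends removed gave 689 higher and 328 lower, and the block without control 3, with few residual degrees of freedom, 1118 higher and 641 lower. Calls fell to 44 without control 1, 68 without control 2, and 56, 41 and 27 without pentanoate 1, 2 and 3. Of the 41 lists 4 were called, and the neuronal list alone held with an estimated correlation. With the block and an estimated correlation it was not called (adjusted p = 0.17), and 0 lists were. Without control 1 or control 3, 7 lists were called, and without control 2 or pentanoate 1, 2 lists.

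The acids, whose carbon chains differ in length by 1 carbon, were compared directly at the same dose and time. Several muscle genes that fell with butyrate were higher with pentanoate than with butyrate. Mymk differed by 2.82 (SE 0.41, adjusted p = 0.0073), Acta1 by 2.16 (SE 0.23, adjusted p = 0.00197), Acta2 by 0.96 (SE 0.10, adjusted p = 0.00197) and Lmod1, a smooth muscle leiomodin, by 1.32 (SE 0.17, adjusted p = 0.00449), all higher with pentanoate. H19, an imprinted non-coding RNA, was higher with pentanoate by 1.36 (SE 0.18, adjusted p = 0.00526), at 801 ± 56.8 against 312 ± 91.2 CPM (SD, n = 3 each), and the Notch modifier Lfng by 0.77 (SE 0.11, adjusted p = 0.00656). Lower with pentanoate were Cxcl1 (−1.64, SE 0.15, adjusted p = 0.00124), Ccng1 (−1.07, SE 0.15, adjusted p = 0.0073), Pgam1 (−0.61, SE 0.09, adjusted p = 0.0068) and the unnamed protein-coding gene 2610528A11Rik (−3.14, SE 0.45, adjusted p = 0.00712). Cck (−5.07, SE 0.78) and the lactate dehydrogenase gene Ldha (−0.63, SE 0.09) were lower too, with adjusted p = 0.00823 and 0.0073, and without pentanoate 1 both missed the threshold (0.0521). Myod1 was higher with pentanoate by 0.82 (SE 0.17, adjusted p = 0.0304), a call lost without butyrate 2, butyrate 3 or any pentanoate library (0.0598 to 0.134). Myog differed by 2.43 (SE 0.74, adjusted p = 0.11, and 0.000548 with the block) and Myh3 by 1.76 (SE 0.80, adjusted p = 0.287, and 0.0266 with the block).

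By list, smooth muscle and myofibroblast markers were higher with pentanoate than with butyrate in 4 of 12 cases (10 adjusted over the list alone, 11 with the block), with a median of 0.87 (adjusted p = 5.3e-08, and adjusted p = 0.15 with an estimated correlation). The sarcomere list had 1 of 30 higher (10 adjusted over the list alone, 10 with the block) and a median of 0.52 (adjusted p = 3e-06, and adjusted p = 0.18 with an estimated correlation). The late myogenic list had 2 of 23 higher (8 adjusted over the list alone, 8 with the block) and a median of 0.40 (adjusted p = 3.3e-06, and adjusted p = 0.15 with an estimated correlation), and with the filter at a mean of 5 CPM it was not called (adjusted p = 0.053). Glycolysis and hypoxia response genes were lower in 4 of 31 cases (19 adjusted over the list alone, 14 with the block), with a median of −0.36 (adjusted p = 4e-09, and adjusted p = 0.06 with an estimated correlation). The p53 targets were lower in 5 of 25 cases (12 adjusted over the list alone, 12 with the block), with a median of −0.39 (adjusted p = 5.5e-08, and adjusted p = 0.093 with an estimated correlation). Inflammatory mediators were lower in 4 of 20 cases (9 adjusted over the list alone, 8 with the block), with a median of −0.55 (adjusted p = 2e-05, and adjusted p = 0.086 with an estimated correlation). Oxidative stress genes and metallothioneins were lower in 5 of 28 cases (9 adjusted over the list alone, 10 with the block), with a median of −0.26 (adjusted p = 1.4e-06, and adjusted p = 0.15 with an estimated correlation). The genes commonly raised by deacetylase inhibitors were lower in 2 of 17 cases (1 higher and 5 lower adjusted over the list alone, 1 higher and 4 lower with the block), with a median of −0.27 (adjusted p = 0.0018, and adjusted p = 0.093 with an estimated correlation). Neuronal markers, 1 higher and 2 lower of 9 (1 and 5 adjusted over the list alone, 1 and 4 with the block), had a median of −0.54 (adjusted p = 0.027, and adjusted p = 0.15 with an estimated correlation), and the list was not called without control 3 (0.053), butyrate 2 (0.086) or pentanoate 3 (0.078).

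**Figure D3:**
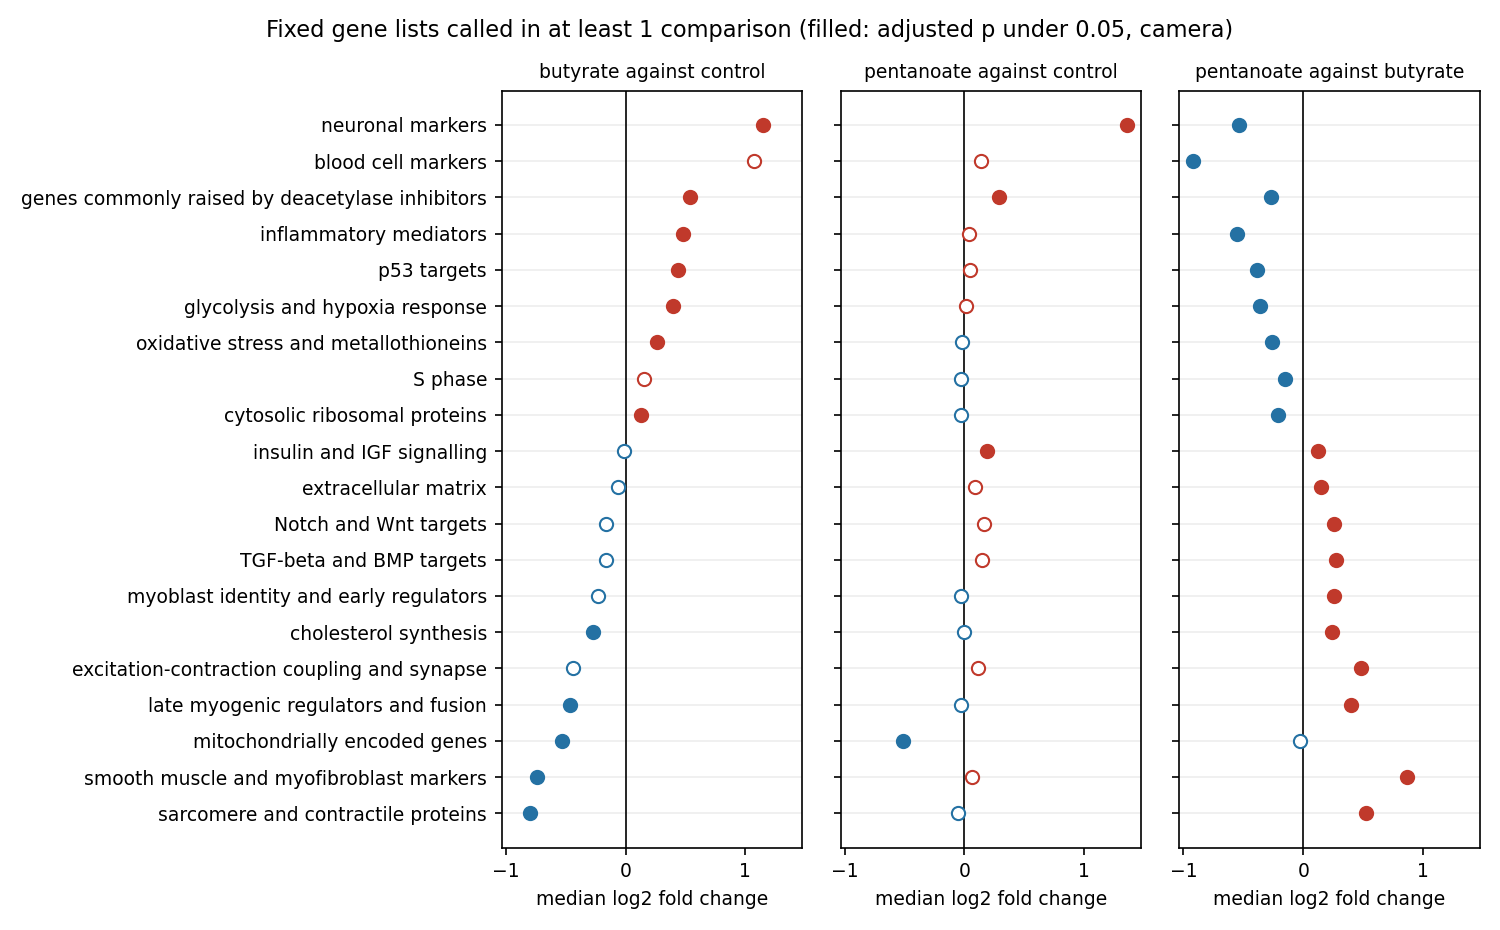
Median log2 fold change (x axis) of the 20 fixed gene lists called in at least 1 comparison (y axis), in a panel per comparison, with red for medians above 0, blue for medians below 0, and filled points for lists called by camera with the preset correlation. Muscle lists lie left of 0 with butyrate, near 0 with pentanoate, and right of 0 for pentanoate against butyrate.

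Several genes did not differ between the acids by this test. Intervals of the difference, pentanoate minus butyrate on the log2 scale, were −0.38 to 0.07 for H1f0, −0.41 to 0.01 for Hdac1, −0.16 to 0.28 for Hdac2, −0.38 to 0.19 for Mki67 and −0.55 to 0.08 for Myf5, with adjusted p from 0.312 to 0.836. A missed threshold does not show that the acids act alike on these genes. For Pdk4 (0.07 to 0.46) the unadjusted interval lay above 0 with an adjusted p = 0.149. For Cdkn1a (−1.15 to −0.30), Ccnd1 (−0.93 to −0.16) and Slc16a1 (−0.62 to −0.14) the unadjusted intervals lay below 0 with adjusted p = 0.0698, 0.128 and 0.0864, and with the block all 3 were called (0.00281, 0.0016 and 0.021). Of all genes tested, 7992 (56.8%) had a direct interval within 1.5-fold in either direction. The direct comparison called 481 genes, 255 higher with pentanoate and 226 lower (53% higher, and 41.1% with upper-quartile scaling), and the block called 1483. At a change of at least 2-fold, 66 of the 481 were higher with pentanoate and 118 lower. Leaving out butyrate 1, 2 or 3 left 253, 95 and 101 calls, and leaving out pentanoate 1, 2 or 3 left 75, 176 and 166. Of the 41 lists 19 were called, 10 higher and 9 lower, and 0 were called with an estimated correlation, while fry called 21.

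Most genes called for butyrate had a fitted fold change of the same sign and smaller size with pentanoate, though 1491 of them were not called for pentanoate. Of the 905 rises called for butyrate, 849 (93.8%) had the same sign with pentanoate, and of the 696 falls 589 (84.6%), where unchanged groups against the same controls gave on average 62.5% and 65.7%. The change was smaller with pentanoate for 95.4% of the rises and 98.7% of the falls, and median log2 changes were 1.15 and 0.53 for the rises and −0.57 and −0.17 for the falls. Choosing genes by their butyrate call favours a smaller change with pentanoate, and no chance value was simulated for these shares. When genes were chosen without the libraries of a number and measured in that number alone, pentanoate reached 0.48 to 0.51 of the butyrate change for rises and 0 to 0.18 for falls. For these falls the mean log2 change with pentanoate was −0.21, −0.19 and 0 in numbers 1, 2 and 3. The value of 0 was read against control 3, which stood apart. A direct difference was called for 204 of the rises (22.5%) and 198 of the falls (28.4%), and the interval of the difference lay within 1.5-fold for 221 and 265 of them.

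Shared calls numbered 107 among rises and 3 among falls, and 0 genes were called in opposite directions. Independent lists give 7.08 and 0.148, which leaves out the shared controls and is not the value for unchanged groups. The simulated unchanged groups had 0 calls for pentanoate, so they give no chance value for an overlap, and the excess is not taken as a shared effect. The fold changes of both acids over all tested genes correlated at r = 0.718 (Spearman's rho 0.605), against 0.504 on average for simulated unchanged groups (highest 0.526). Their covariance was 0.166 against a simulated 0.0404 (highest 0.0435). These simulations hold no effect of the replicate number. With the block and such an effect in the simulated groups, chosen after the data were seen, the covariance was 0.166 against 0.0286 (highest 0.0315). Fold changes against separate control libraries for each acid were not compared, so part of the excess may come from the shared controls. Both kinds of simulation give each gene a single spread for all groups, while control 3 stood further from its group than the other libraries did. The simulated shared part may therefore be too small. The common fraction of the butyrate change seen with pentanoate, with the simulated shared part removed, was 0.47 (jackknife SE 0.07). It was 0.47 with the block and 0.49 without control 3.

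Genes called for pentanoate and not for butyrate were Ncf4, Rac3 and Jak3, named here after their values were seen because there were 3. Whether their calls held when a library was left out was not examined. Ncf4, a subunit of the phagocyte NADPH oxidase, rose by 1.66 with pentanoate (adjusted p = 0.0084) against −0.12 with butyrate, a direct difference of 1.78 (SE 0.23, adjusted p = 0.0045). For Rac3 and Jak3 the direct difference was 0.40 (SE 0.17, adjusted p = 0.23) and 0.69 (SE 0.22, adjusted p = 0.13), and it was not called. Stmn2 also rose further with pentanoate than with butyrate, by 0.50 (SE 0.10, adjusted p = 0.02).

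**Figure D4:**
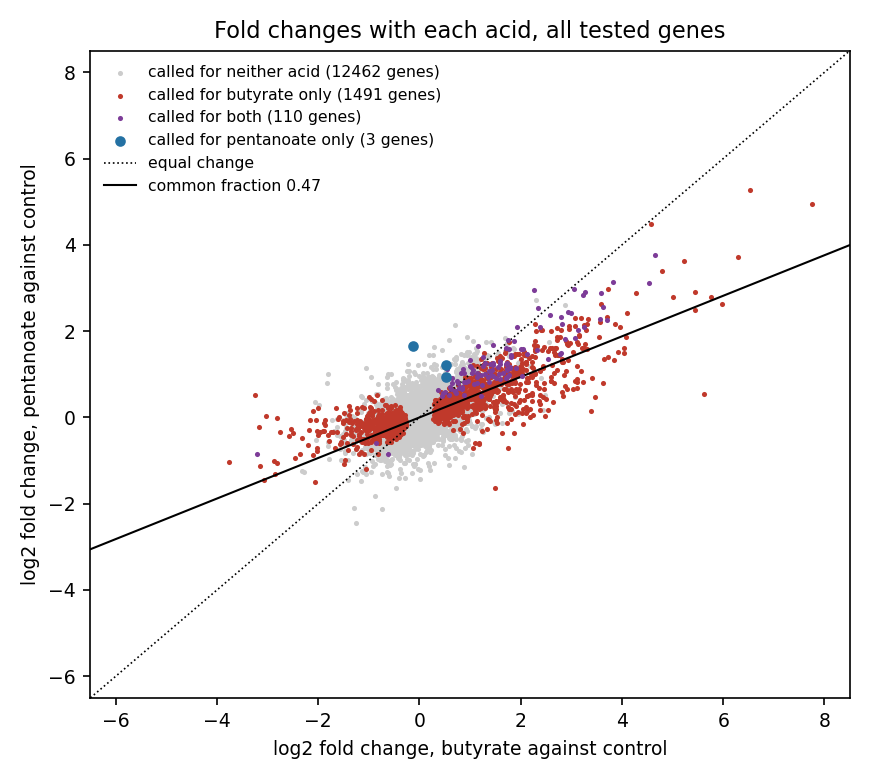
Fitted log2 fold change against control with butyrate (x axis) and pentanoate (y axis) for 14066 genes, coloured by whether a gene was called for neither acid (12462), butyrate alone (1491), both (110) or pentanoate alone (3). The dotted line marks equal change and the solid line the common fraction of 0.47, and most genes called for butyrate lie between the solid line and the x axis or near the solid line.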

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

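The replicate block for the common fraction, the block without control 3, the block with GC content and length trends removed, the table without mitochondrially encoded genes and library omissions for 37 of the 41 lists were chosen after the results were seen. No gene named here and no list called in the first test was called in the other direction in the settings run for it, and 42 counts of calls moved by over 1.5 times and 42 did not. Among list tests of called lists 267 kept the call and 58 lost it, and of lists not called 49 gained a call and 757 did not. Among tests of called named genes 833 kept the call and 238 lost it, and of named genes not called 43 gained a call and 416 did not. Apart from the blocked values printed beside results, the block called the heat shock list between the acids (adjusted p = 0.037 against 0.065 without it, and adjusted p = 0.21 with the block and an estimated correlation), and at the preset correlation it changed no other list call. With the block and an estimated correlation 0 lists were called in any comparison. The common fraction was 0.44 to 0.51 in 13 alternatives (0.47 with the block). Its jackknife error comes from 9 of these values, so their lying within that error is no separate check. Scaling moved the median log2 change of all tested genes to between −0.035 and 0.028.

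For butyrate against control, the 1601 calls became 2916 with the replicate block, 1023 with a filter at a mean of 5 CPM, 1004 with a fit of these 2 groups alone, and 646 at a change of at least 2-fold. They ranged from 753 without butyrate 2 to 2285 without control 3. The block without control 3 gave 4830, with few residual degrees of freedom, and the block with GC content and length trends removed gave 4137. For pentanoate against control, the 113 calls became 514 with the block, 324 with the DESeq2 Wald test, 278 without a filter, 25 with these 2 groups alone and 72 at a change of at least 2-fold. They ranged from 27 without pentanoate 3 to 139 without control 3, and were 1759 with the block without control 3 and 1017 with the block and trends removed. For pentanoate against butyrate, the 481 calls became 1483 with the block, 884 with the DESeq2 Wald test, 319 with the filter at 5 CPM, 1365 with these 2 groups alone and 184 at a change of at least 2-fold. They ranged from 75 without pentanoate 1 to 253 without butyrate 1, and were 4632 with the block without control 3 and 2595 with the block and trends removed.

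For butyrate, the late myogenic list had adjusted p = 0.32 with an estimated correlation and 0.17 with the filter at 5 CPM, and the sarcomere list 0.32 with an estimated correlation. The S phase list had 0.0032 with the block, 0.011 with the filter at 5 CPM, and 0.0068 (without butyrate 1) to 0.78 (without control 1) over omissions, and the G2 and M phase list 0.031 (without control 1) to 0.78 (without butyrate 2). For pentanoate, omissions gave 0.045 (without control 3) to 0.72 (without pentanoate 3) for the sarcomere list, 0.049 (without control 1) to 0.72 (without pentanoate 3) for S phase, and 0.021 (without control 1) to 0.91 (without pentanoate 1) for G2 and M phase. Between the acids, the late myogenic list had 0.15 with an estimated correlation and 0.053 with the filter at 5 CPM, and the sarcomere list 0.18 with an estimated correlation. The S phase list between the acids had 0.76 with an estimated correlation, 0.6 with fry, and 4.9e-05 (without pentanoate 2) to 0.86 (without pentanoate 1) over omissions. With an estimated correlation, 3 fixed gene lists were called for butyrate against control, 1 for pentanoate against control and 0 for pentanoate against butyrate, and fry called 2 for pentanoate against control. Over omissions the fixed gene lists called for pentanoate against control numbered 2 (without control 2) to 7 (without control 1).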

Other observations

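Further lists differed in ways not described above. With butyrate, cholesterol synthesis genes, with 1 rise and 4 falls among 26 (2 and 5 adjusted over the list alone, 2 and 7 with the block), had a median of −0.27 (adjusted p = 0.0043, and adjusted p = 0.42 with an estimated correlation). Cytosolic ribosomal proteins, with 1 of 67 rising (0 adjusted over the list alone, 6 with the block), had a median of 0.13 (adjusted p = 0.0031, and adjusted p = 0.55 with an estimated correlation), and the list was not called without butyrate 2 (0.055). The ribosomal pseudogene Rps26-ps1 was counted at 15.2, 58.5 and 184 CPM in controls 1 to 3. How reads were shared between near-identical genes is unknown, so values of ribosomal protein genes are uncertain in every comparison. The list of short-chain fatty acid uptake and activation, with 3 rises and 1 fall among 13 (4 and 1 adjusted over the list alone, 5 and 1 with the block), had an adjusted p = 0.2, and 0.045 without control 3 (adjusted p = 0.62 with an estimated correlation in all 9 libraries). With pentanoate, 9 lists that were not called in all 9 libraries were called at the preset correlation when a library was left out, and none of them was called with an estimated correlation in all 9. The sarcomere (0.045 without control 3), S phase and G2 and M phase lists (0.049 and 0.021 without control 1) are described above. Oxidative phosphorylation genes, 0 of 74 called (0 adjusted over the list alone), had a median of 0.00 (adjusted p = 0.92, and adjusted p = 1 with an estimated correlation), and −0.07 without control 3 (9.8e-05, again 0 called). Cytosolic ribosomal proteins, 0 of 67 called (2 falls adjusted over the list alone, 3 with the block), had a median of −0.03 (adjusted p = 0.16, and adjusted p = 0.99 with an estimated correlation), and −0.09 without control 3 (1.2e-05, again 0 called). Fatty acid synthesis genes, 0 of 21 called (0 adjusted over the list alone, 1 rise with the block), had a median of 0.05 (adjusted p = 0.23, and adjusted p = 0.99 with an estimated correlation), and 0.17 without control 3 (0.0091, again 0 called). Interferon response genes rose in 2 of 26 cases (2 adjusted over the list alone, 3 with the block), with a median of 0.04 (adjusted p = 0.13, and adjusted p = 0.83 with an estimated correlation), and the list was called without control 3 (0.0053) or pentanoate 2 (0.038). The extracellular matrix list, 0 of 44 called (3 rises adjusted over the list alone, 5 with the block), had a median of 0.09 (adjusted p = 0.13, and adjusted p = 0.83 with an estimated correlation), and was called without control 1 (0.034) or pentanoate 2 (0.025). TGF-beta and BMP targets, 0 of 27 called (5 rises adjusted over the list alone, 6 with the block), had a median of 0.15 (adjusted p = 0.13, and adjusted p = 0.64 with an estimated correlation), and were called without pentanoate 3 (0.034).

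Between the acids, the excitation-contraction coupling and synapse list was called higher with pentanoate at the preset correlation (adjusted p = 1e-04, and adjusted p = 0.15 with an estimated correlation). Its median was 0.48, and 1 of its 24 genes was called higher (11 and 1 lower adjusted over the list alone, 12 and 1 with the block). TGF-beta and BMP targets were higher in 4 of 27 cases (13 and 1 lower adjusted over the list alone, 10 and 2 with the block), with a median of 0.27 (adjusted p = 2e-05, and adjusted p = 0.093 with an estimated correlation). Notch and Wnt targets, 4 higher and 1 lower of 30 (7 and 1 adjusted over the list alone, 11 and 1 with the block), had a median of 0.26 (adjusted p = 0.001, and adjusted p = 0.086 with an estimated correlation). Myoblast identity genes were higher in 5 of 23 cases (7 adjusted over the list alone, 8 with the block), with a median of 0.26 (adjusted p = 0.0081, and adjusted p = 0.15 with an estimated correlation), and cholesterol synthesis genes in 2 of 26 (7 adjusted over the list alone, 7 and 1 lower with the block), with a median of 0.24 (adjusted p = 3.5e-05, and adjusted p = 0.18 with an estimated correlation). Cytosolic ribosomal proteins were lower in 2 of 67 cases (2 adjusted over the list alone, 9 with the block), with a median of −0.21 (adjusted p = 6.5e-08, and adjusted p = 0.2 with an estimated correlation), and blood cell markers in 1 of 5 (2 adjusted over the list alone), with a median of −0.92 (adjusted p = 0.0081, and adjusted p = 0.13 with an estimated correlation). The extracellular matrix list (median 0.15, 4 higher and 2 lower of 44, the same adjusted over the list alone, 14 and 5 with the block) had an adjusted p = 0.031, and adjusted p = 0.49 with an estimated correlation, and was not called without butyrate 2 (0.12), pentanoate 1 (0.054) or pentanoate 3 (0.13). The insulin and IGF list (median 0.12, 3 higher and 1 lower of 19, 4 and 1 adjusted over the list alone, 5 and 2 with the block) had an adjusted p = 0.049, and adjusted p = 0.26 with an estimated correlation, and was not called without control 3 (0.053), butyrate 2 (0.059) or pentanoate 1 (0.057). The S phase list, 0 of 41 called (0 adjusted over the list alone), had a median of −0.15 (adjusted p = 0.018, and adjusted p = 0.76 with an estimated correlation), and was not called without butyrate 2 (0.24) or pentanoate 1 (0.86).

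Of the tests of explanations that follow, those of a GC content trend in control 3 and of a batch shared by the libraries numbered 3 were chosen only after the result was seen, and so were the block with GC content and length trends removed, the block without control 3 and the covariance with the block. A test of background reads was also chosen after the result was seen.

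With pentanoate 97.3% of the calls were rises, and simulated libraries with as many rises as falls gave 53.5%, which argues against a difference in power under the simulated settings. Receptor genes taken as background had a mean CPM with pentanoate of 0.84 times that in control, so the background was not higher with pentanoate. The median log2 change of all tested genes was −0.008, but scaling centres most genes, so this decides nothing and a shift in scaling stays open. With the block and GC content and length trends removed rises were 67.7% of the calls (689 rises, 328 falls), and with the block without control 3 they were 63.6% (1118 and 641), against 82.3% with the block alone (423 and 91). Of the 113 calls the first kept all and the second 112, but 110 of these calls are rises, so keeping them does not bear on the share. The share of rises was lower in both settings, so such trends or control 3 may add to the excess. Both settings also gave more calls than the block alone, so how much they add stays open.

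Control 3 stood apart from controls 1 and 2. Its log2 ratio to them rose with the deposited gene length at rho = 0.2 over genes, against 0.11 for control 1 to control 2. Longer genes were thus relatively higher in control 3, but the test of degraded RNA took the size of rho and not its sign. That size fell between the limits set beforehand, so this test cannot decide on degraded RNA. The mitochondrial share of libraries numbered 3 exceeded that of their groups by at most 0.24 percentage points for butyrate and pentanoate, against 1.8 for control 3. Over genes, the deviations of control 3 correlated with those of butyrate 3 (r = 0.37) and pentanoate 3 (r = 0.29). Those of control 2 did so with butyrate 2 (r = 0.39) and pentanoate 2 (r = 0.40), so this is not particular to the number 3. The chi-square per degree of freedom was 8.04 to 12.6 in pairs with butyrate 3 or pentanoate 3, against 46.3 and 60.7 with control 3. These values argue against a batch of equal size in all libraries numbered 3 as the whole cause, and a batch as a part stays open. The log2 ratio of control 3 to controls 1 and 2 followed GC content at rho = −0.6 (−0.16 for control 1 to control 2). After GC trends were removed the variance ratio was 3.11 against 5.06 before, so a GC trend may be a part and not the whole.

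Pentanoate fold changes followed those of butyrate at a lower size, and the observed covariance was 3.82 times the highest of the simulated unchanged groups. It was 5.26 times the highest with the block and a replicate effect in the simulated groups. Under the simulated settings this argues against shared controls as the whole cause. Those settings give control 3 no larger spread than other libraries, so both ratios may be too high. Without control 3 the common fraction was 0.49. A single weaker effect of the same kind was tested as a fraction shared by all genes, which would leave no list departing from the common fraction. At the preset correlation 17 of 41 lists departed from it (20 with the block). Among them were ribosomal proteins (camera, adjusted p = 1.3e-05), glycolysis and hypoxia response (9.8e-05) and p53 targets (5e-04). The sarcomere and smooth muscle lists departed too, and the larger adjusted p of these was 0.0096. With an estimated correlation those 5 had adjusted p = 0.3, 0.17, 0.26, 0.44 and 0.29. By gene, 4 departed, 0.028% of those tested, and 307 (2.2%) did with the block. The fraction of 0.47 was fitted to the same data, and with 0.44 in its place 16 lists departed (19 with the block). Other fractions were not tried, and departures were not examined without control 3. The values argue against a single fraction as the whole account at the preset correlation, as do the held-out fractions of 0.48 to 0.51 for rises and 0 to 0.18 for falls. They cannot decide on a weaker effect of the same kind whose size differs between genes, since each acid was given at a single dose.

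Each comparison of 6 libraries allows 10 splits into 3 and 3, too few for a share under 0.05, with a smallest share of 0.1. Of the 10 splits, 4 part all 3 same-numbered pairs, so splits that respect the pairing are fewer still. For butyrate against control the real split gave 1004 calls, and the highest other split 1. For pentanoate against control these were 25 and 0, and for pentanoate against butyrate 1365 and 0. In each comparison 1 split, the real one, reached the real count.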
